A study of Apis laboriosa and Apis dorsata with 2 samples.

How the data were processed

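RNA-seq was carried out on worker bees of 2 giant honey bee species. Apis laboriosa, the Himalayan giant honey bee, was sampled at 2150 m, and Apis dorsata, the giant honey bee, at 570 m, per the labels. The tissue was the body without the abdomen (the labels write belly). Per the labels' protocols, RNA from 3 bees of a species was isolated separately with TRIzol and mixed in equal amounts before library preparation, so that each species has 1 library. The libraries were made with a NEBNext Ultra RNA kit and read as pairs of 150 nt reads on an Illumina HiSeq, per the labels' protocols. Species, altitude, collection place and library therefore all change together between the libraries.

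For each species the authors deposited a table with 1 line per feature, holding an estimated count of reads and an FPKM value (fragments scaled to feature length and library total). RSEM, which assigns reads to transcripts and estimates their number, is named in the submitters' processing notes without a version. The aligner, the assembly that was counted on and any filter are not given in the sources used here. The estimated counts as deposited were whole numbers for all but 0.348% of the A. laboriosa features and 0.473% of the A. dorsata features. All 183389 identifiers were a species prefix followed by a component number and a gene number, the form in which de novo transcriptome assemblers name their products. No identifier occurred in both tables. Once the prefix was removed, 63519 component and gene numbers occurred in both, but they did not pair features. Among the 4396 same-numbered pairs with an effective length of at least 500 nt and at least 10 counts in both tables, 4.50% had lengths within 5% of each other. After shifting one list by 1 place the share was 4.55%. None of the identifiers matched a gene, locus tag, symbol or accession in the RefSeq gene table of A. laboriosa (assembly ASM1406632v1), and the files pair no feature with a gene name or a sequence. A feature was therefore compared with features of its own library, and the libraries were compared by their distributions. The planned log2 ratios per gene were not computed, and 0 of the 240 symbols in the 17 gene lists written before the data were examined could be looked up. Gene names and pathways are not analysed here.

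From the deposited values the following were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with figures from matplotlib 3.10.9. The total of a library is the sum of its estimated counts. A feature was called detected at 10 counts or more. Shares of counts carry exact (Clopper-Pearson) 95% intervals and single counts exact Poisson 95% intervals. Estimated counts were rounded to whole numbers for intervals and thinning. Reads carried no molecular identifiers, so these intervals cover counting error only. Depth was matched by binomial thinning, calculated exactly as the expected number of features left at a count minimum, with its SD. Thinning does not remake the assembly.

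The effective length of a feature, the number of positions at which a fragment can start, was computed as the count × 1e+09 divided by the FPKM and the library total. This relation was checked on the values. For transcripts well above the fragment length, an effective length is a whole transcript length minus the mean fragment length plus 1. Such features with 1 transcript should therefore share the same decimals. Of 232 A. laboriosa features above 400 nt whose rounding error was under 0.02 nt, 83.2% lay within 0.03 nt of 0.39 after the decimal point. In A. dorsata 82.5% of 160 such features lay within 0.03 nt of 0.57. Evenly spread decimals would give 6%. The true length of such a feature exceeds its effective length by about 1 fragment. Shorter features were not checked. The shortest effective lengths were 2.40 nt in A. laboriosa and 1.44 nt in A. dorsata, and FPKM values of such short features rest on a few possible positions.

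The computations were tested on simulated data, in which counts were drawn for the 106176 A. laboriosa features at the A. dorsata depth with 1 feature raised to a large known share of the counts and 200 features changed by known folds. The 6 quantities compared were recovered with a relative error of at most 0.998%. Among features with at least 10 counts, lengths computed from FPKM rounded to 2 decimals had a median error of 0.103%. The FPKM values were simulated with the same formula, so the length check covers rounding and not the formula. Features under 10 counts were not covered by the length check.

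With 1 library per species there is no replicate error. No p-value, SD between samples or count of changed genes is given, and a difference between the libraries cannot be assigned to the species, the altitude or the individual pools. The rule for single features, fixed before the data were examined, named the 2 with the most counts in each library when identifiers could not be paired. Alternatives fixed at the same time were other count and FPKM minimums, thinning to the smaller library, leaving out the highest features or those under 10 counts, and FPKM in place of counts. Splits by length and level, abundance at a given rank, and the totals and FPKM rescaling without the highest feature of a library, and thinning to the counts outside the highest A. dorsata feature, were chosen after seeing the data.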

Results

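The tables described the transcriptomes of worker bees of Apis laboriosa, a giant honey bee of the high Himalaya, and of its relative Apis dorsata, each as 1 library from 3 pooled bees. The title of the series places the comparison in the study of adaptation to high elevation. The A. laboriosa table listed 106176 assembled features in 98393 components, with a total of 65478506 counts. The A. dorsata table listed 77213 features in 68882 components, with 61355778 counts. The totals differed by 1.07-fold and the number of listed features by 1.38-fold. Features with a count of 0 made up 15.3% of the A. laboriosa list (16224 features) and 17.7% of the A. dorsata list (13690 features). For scale, the RefSeq annotation of A. laboriosa holds 9783 protein-coding genes, so that both lists were many times longer than the set of coding genes. There were no replicates, and the values below describe these libraries.

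The first question was how transcript abundance was distributed over the features in each species. In A. dorsata 1 feature, c34801_g1, took 14177610 counts, which was 23.1% of the library (95% interval 23.10 to 23.12, counting error only). Its FPKM was 28302 and its effective length 8165 nt. The next A. dorsata feature, c38187_g1, held 1704180 counts, or 2.78% of the library, at 17055 FPKM and 1629 nt, so that c34801_g1 exceeded it by 8.32-fold in counts. No A. laboriosa feature approached this share. The highest there, c18803_g1, held 1928532 counts, 2.95% of the library (95% interval 2.941 to 2.949), at 39461 FPKM and an effective length of 746 nt. The second, c44877_g2, held 1403702 counts, or 2.14%, at 5340 FPKM and 4014 nt. Which genes these features represent was not analysed here.

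The dominant A. dorsata feature also stood apart from other long features by its FPKM. The libraries were similar in long features, with 636 of at least 5000 nt in A. laboriosa and 622 in A. dorsata, and their median FPKM was 15.9 and 13.2. The highest of these in A. laboriosa reached 892 FPKM, and c34801_g1 exceeded it by 31.7-fold. Within A. dorsata the second highest long feature reached 1326 FPKM, 21.3-fold below c34801_g1. By FPKM the most abundant features of both libraries were short. The highest in A. laboriosa had 55632 FPKM and an effective length of 317 nt, and the highest in A. dorsata had 62737 FPKM and 303 nt. In A. dorsata c34801_g1 was the third feature by FPKM.

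**Figure D1:**
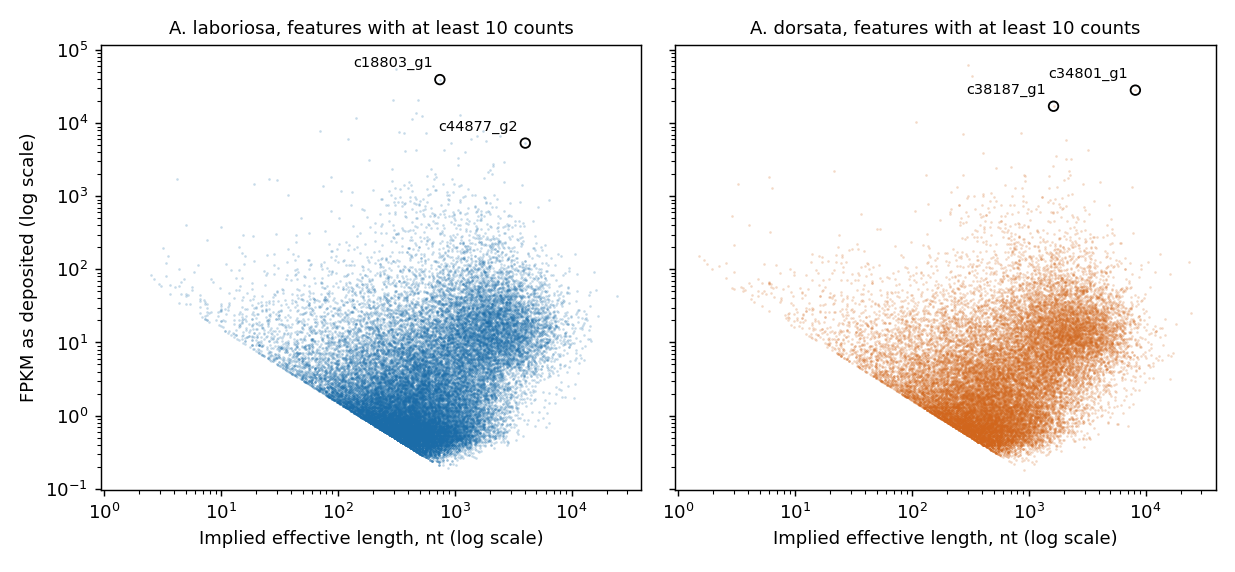
Effective length computed from the deposited counts and FPKM (x axis, nt, log scale) against deposited FPKM (y axis, log scale), with 1 point per feature of at least 10 counts, for A. laboriosa (left) and A. dorsata (right). Circles mark the 2 features with the most counts in each library, and c34801_g1 lies alone at 8165 nt and 28302 FPKM, above the other long features.

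Counts were more concentrated in A. dorsata, and c34801_g1 accounted for most of that difference. The 10 highest features held 34.9% of the A. dorsata counts (95% interval 34.87 to 34.89) and 15.2% of the A. laboriosa counts (15.23 to 15.24). The 100 highest held 50.4% and 35.6%. It took 96 features to reach 50% of the A. dorsata counts and 335 to reach 50% of the A. laboriosa counts. When the single highest feature of each library was left out, the 10 highest held 16.1% and 13.5%, and the number of features holding 50% became 350 in A. dorsata and 371 in A. laboriosa. Ranked by FPKM instead of counts, the 10 highest features held 25.8% of the summed FPKM in A. dorsata and 21.6% in A. laboriosa, the same order. The order of the other measure turned, with 50% of the summed FPKM held by 367 A. dorsata and 225 A. laboriosa features.

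From about rank 10 to rank 10000 the libraries had nearly the same abundance profile once the dominant feature was set aside. The feature at rank 100 stood at 1035 CPM (counts scaled to the library total) in A. laboriosa (95% interval 1027 to 1043) and at 808 in A. dorsata, a ratio of 1.28. Scaled instead to the 47178168 A. dorsata counts outside c34801_g1, it stood at 1051 CPM (1042 to 1061). That at rank 1000 stood at 161 in A. laboriosa (158 to 164) and at 165 in A. dorsata on this scale (161 to 169), that at rank 5000 at 25.02 (23.8 to 26.3) and 27.4 (26.0 to 29.0), and that at rank 10000 at 4.17 (3.69 to 4.69) and 4.20 (3.63 to 4.82). These intervals treat the feature at a rank as a single Poisson count. They do not measure the counting error of the value at that rank, so their overlap does not show that the profiles are equal. With the highest feature left out of both totals, the ratio of A. laboriosa to A. dorsata was 0.611 at rank 2, 1.05 at rank 10, 1.01 at ranks 100 and 1000, 0.94 at rank 5000 and 1.02 at rank 10000. Lower down the profiles separated, with ratios of 1.24 at rank 20000 and 1.61 at rank 30000, where features had 35 against 21 counts and 13 against 6 counts.

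**Figure D2:**
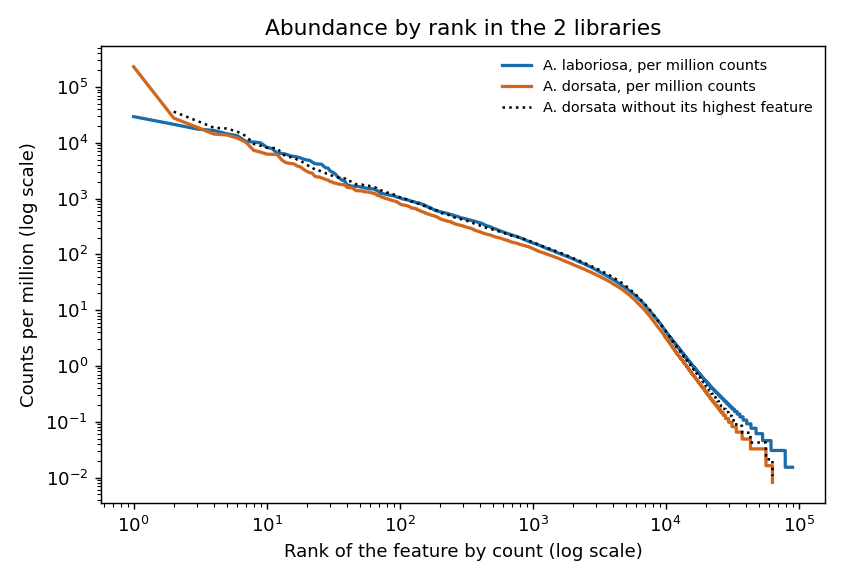
CPM (y axis, log scale) against the rank of a feature by count (x axis, log scale) in the A. laboriosa library (blue) and the A. dorsata library (orange), and in A. dorsata scaled to the counts outside its highest feature (dotted). The solid lines differ by 1.28-fold at rank 100, and the dotted line lies above A. laboriosa at rank 2 (36122 against 21438 CPM) and close to it at ranks 100, 1000 and 10000.

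The same feature shifted the deposited FPKM scale. Leaving it out raises every other A. dorsata FPKM by 1.30-fold. At a minimum of 60 FPKM, 1493 A. laboriosa and 1121 A. dorsata features passed as deposited, a ratio of 1.33, and 1525 A. dorsata features passed after this rescaling, a ratio of 0.979. At a minimum of 1 FPKM the numbers were 49605 in A. laboriosa, 42340 in A. dorsata as deposited and 47223 after rescaling. Most of these features had under 10 counts, and with at least 10 counts 23116 and 19985 passed as deposited. The median effective length between 1 and 3 FPKM was 35.0 nt in A. laboriosa and 45.3 nt in A. dorsata. At 15 FPKM the numbers were 6091, 6165 and 8171, so that the ratio moved from 0.988 to 0.745. They too had no count minimum. The median effective length as deposited was 1295 and 903 nt between 15 and 60 FPKM. Between 3 and 15 FPKM, below that minimum, it was 21.4 and 14.8 nt. At 3 FPKM the rescaled ratio was 0.853 without a count minimum and 0.994 with at least 10 counts. The rescaled ratio at 3 FPKM therefore depends on features with few counts. At 1 and 15 FPKM the rescaled ratio was not computed with a count minimum, so this was not tested there. Features of at least 1000 FPKM numbered 82 in A. laboriosa and 49 in A. dorsata, a ratio of 1.67, and 66 in A. dorsata after rescaling, a ratio of 1.24. Their median effective lengths as deposited were 640 and 867 nt. The 82 and 49 features held 29.3% and 41.9% of the counts, and 27.2% and 24.4% with the highest feature of each library left out. Both pairs of shares keep the deposited FPKM scale. They were not computed for the 66 A. dorsata features that passed after rescaling.

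The second question was how many transcripts were detected in each species. At 10 counts or more A. laboriosa had 34381 features and A. dorsata 25977, a ratio of 1.32. The ratio was 1.13 at 100 counts (13907 and 12255) and 1.12 at 1000 counts (6398 and 5688). Thinning A. laboriosa to the A. dorsata total left 33423 ± 24.2 features (SD of thinning) at 10 counts. Thinning it to the A. dorsata counts outside c34801_g1 left 29870 ± 34.6, a ratio of 1.15. At the minimum of 100 counts the same thinning left 12501 ± 11.2 features, a ratio of 1.02.

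**Figure D3:**
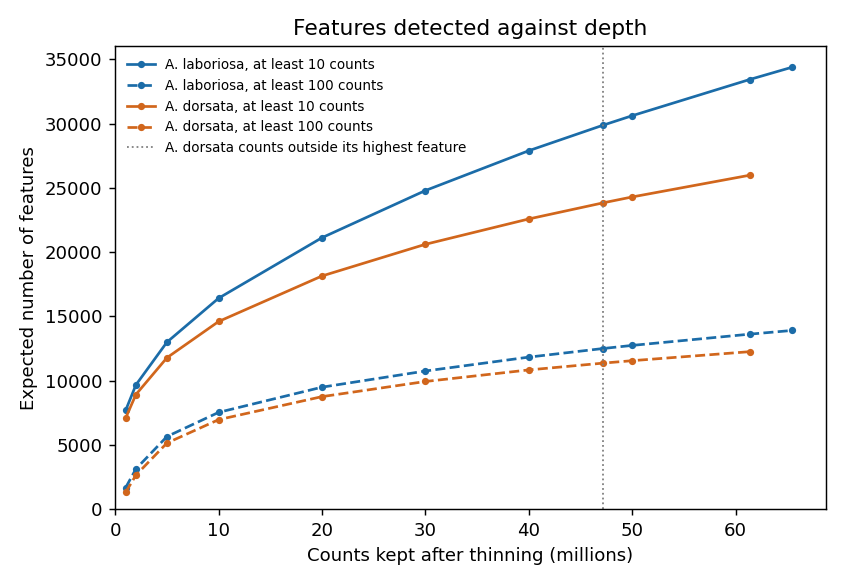
Expected number of features (y axis) with at least 10 counts (solid) or at least 100 counts (dashed) against the number of counts kept after thinning (x axis) in A. laboriosa (blue) and A. dorsata (orange). The dotted vertical line marks the 47178168 A. dorsata counts outside c34801_g1, where A. laboriosa has 29870 features at 10 counts against 25977 in the complete A. dorsata library.

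At the deposited depths the additional A. laboriosa features were mostly weakly expressed, while the number of long, well-expressed features was nearly equal. Of the features with at least 10 counts, 19806 in A. laboriosa and 12738 in A. dorsata lay under 3 FPKM, a ratio of 1.55, against 14575 and 13239 at 3 FPKM or more, a ratio of 1.10. After rescaling A. dorsata without c34801_g1 these ratios were 1.75 and 0.994. None of them was matched for depth. Thinning A. laboriosa to the A. dorsata counts outside c34801_g1 left 9903 of its 9904 features of at least 1000 nt. It left 19966 of the 24477 shorter ones, all with at least 10 counts. The ratios under 3 FPKM over all lengths are therefore partly set by depth. Features of at least 1000 nt with at least 3 FPKM numbered 7015 in A. laboriosa and 6752 in A. dorsata, and 7124 in A. dorsata after rescaling without c34801_g1, which turns the order. Among features of that length under 3 FPKM and with at least 10 counts there were 2889 in A. laboriosa against 2094 in A. dorsata, or 1722 after rescaling. Between 500 and 1000 nt the weakly expressed features numbered 5848 and 3635, a ratio of 1.61. At 4000 nt or more, features of any level with at least 10 counts numbered 1121 and 1147. The median effective length of features with at least 10 counts was 540 nt in A. laboriosa and 599 nt in A. dorsata, and at 100 counts it was 1288 and 1418 nt. The mean fragment length, by which effective and true lengths differ, was not given for either library.

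Features under 10 counts carried little of either library, 0.277% of the A. laboriosa counts and 0.192% of the A. dorsata counts. Features of at least 1000 nt with 10 counts or more carried 76.8% of the A. laboriosa counts and 86.3% of the A. dorsata counts, or 82.2% of those outside c34801_g1. Components split into several features numbered 5807 in A. laboriosa, 5.90% of its components, and 5506 in A. dorsata, 7.99% of its components. Their features held 33.7% and 33.6% of the counts, and 34.7% and 43.6% with the highest feature of each library left out.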

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

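With 1 library per species, no replicate could be left out. Differences per gene and per gene list, and their other settings, were not run, because features could not be paired between the species. Across the other 23 alternatives, 20 kept the order of the libraries and 3 turned it. Rounding counts or leaving out features under 10 counts changes too few counts to turn the order of the totals, so the tally is not a measure of robustness. The turned ones were 50% of the summed FPKM in place of counts (225 features in A. laboriosa, 367 in A. dorsata), a minimum of 3 FPKM (23965 and 24095), and the median effective length over all features with a count above 0 (117 and 110 nt). Values are given with A. laboriosa first. The total was 55503499 and 39955233 without the 10 highest features, 65296967 and 61238184 without features under 10 counts, and 63549974 and 47178168 without the highest feature. Features detected were 89952 and 63521 at 1 count, 13907 and 12255 at 100 counts, and 16025 and 14319 at 1 CPM. The share of the 10 highest features became 35.6% and 50.4% for 100 features, 21.6% and 25.8% of FPKM, 15.3% and 34.9% without features under 10 counts, and 13.5% and 16.1% without the highest feature. Without that feature, 350 A. dorsata features held 50% of the counts. At 0.3 FPKM 85267 A. laboriosa features passed, and at 1 FPKM with at least 10 counts 23116 and 19985 did. At 100 counts the median effective length was 1288 and 1418 nt. Leaving out features or raising a minimum moves these values by construction. Depth limits the weak features: at 10 counts the number was still rising with depth in both libraries.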

Other observations

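All tests in this part were chosen after the results were seen. Each species has 1 library, so no biological explanation that rests on species or altitude was tested.

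In A. dorsata 23.1% of the counts fell on c34801_g1, a feature with an effective length of 8165 nt. A transcript equally abundant in A. laboriosa but broken into pieces by its assembly is argued against: the A. laboriosa features at 14151 FPKM or more, which is 50% of its level, numbered 4 and added up to 1843 nt of effective length. If each piece is longer than its effective length by about 1 fragment, a mean fragment of 2107 nt would be needed for these 4 to reach the whole. This is beyond the 1000 nt assumed as an upper bound. Pieces at a lower level are not excluded: those at 9434 FPKM or more numbered 9 and added up to 4520 nt, for which a mean fragment of 456 nt would do. A candidate explanation is RNA of another organism, such as a virus with a polyadenylated genome carried by 1 or more of the pooled bees. Without the sequence of the feature this stays open. The feature stood 21.3-fold above the next A. dorsata feature of at least 5000 nt, but this restates its dominance and does not tell the candidates apart. Ribosomal RNA left in the library also stays open: the longest ribosomal RNA gene annotated for A. laboriosa spans 2340 nt, but it starts at position 1 of its scaffold and may be incomplete, and a precursor would be longer. A bee transcript that differs between the species, places or individual bees was not tested, and a sequence search of this feature would be the first step.

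A. laboriosa had more features with at least 10 counts, 34381 against 25977. Fewer A. dorsata counts outside c34801_g1 do not account for the whole difference with each assembly as deposited, since 29870 ± 34.6 A. laboriosa features were left after thinning to that number of counts; the thinning removed 17.4% of the gap at a minimum of 1 count, 53.7% at 10 counts and 85.1% at 100 counts. An assembly from more reads, with more short pieces, may account for part of the rest. The ratio of A. laboriosa to A. dorsata was 1.03 for features of at least 2000 nt, and after thinning 1.20 between 1000 and 2000 nt, 1.37 between 500 and 1000 nt, 1.14 between 200 and 500 nt and 0.906 below 200 nt. The ratio thus did not increase steadily towards shorter features, and this explanation stays open. More variation among the pooled bees, RNA of other organisms and a larger set of weakly expressed bee transcripts were not tested.

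Both tables list features that were assembled but have a count of 0, although assembly needs reads. One hypothesis was that their reads were given to a sister feature of the same component. The share at 0 in components of several features was 10.1% in A. laboriosa, against 16.0% in components of 1 feature (-5.90 percentage points). In A. dorsata it was 11.7% against 19.1% (-7.37). This comparison cannot decide, because the former made up 12.8% and 17.9% of features but held 33.7% and 33.6% of counts. Of the features at 0, 14846 of 16224 in A. laboriosa and 12074 of 13690 in A. dorsata lay in components of 1 feature. These had no listed sister, which argues against the hypothesis for them, provided that no sister was filtered out. Component numbers ran to 108717 in A. laboriosa and 80995 in A. dorsata, with 98393 and 68882 components listed, so some numbers were absent. For the remaining features at 0 the hypothesis stays open. The lengths of features with a count of 0 cannot be computed, so whether they are very short stays open.

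Counts that were not whole numbers, which RSEM gives where a read matches several features, occurred in 370 A. laboriosa and 365 A. dorsata features. Of these, 366 and 365 lay in components of several features.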
